A study of Saccharomyces cerevisiae with 67 samples.

How the data were processed

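Genomic DNA of 66 yeast samples was compared with DNA of one S288C reference strain on Agilent arrays with 2 dyes. The sample carried Cy3 (green) and the reference Cy5 (red) on every array, without a dye swap. A further array, labelled as the reference strain against itself, was not used, because its reference signals correlated with the median of the other arrays at 0.00557, whereas each of the other 66 arrays reached at least 0.888, and because 40826 of its probes were not well above background in the reference channel.

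Per the file headers, Agilent Feature Extraction 10.5.1.1 made 54 of the 67 files, version 10.7.3.1 made 12 and version 10.1.1.1 made 1, and the submitters' processing notes name the same software. The deposited scanner files give processed and median signals as intensity values, after background subtraction, spatial detrending and linear dye normalization by the authors' software in the case of the processed signals. Their ratio column is deposited as log10 of reference over sample. The deposited value table of the series holds log2 of sample over reference. It was checked against the scanner files on all used arrays and differed from the rescaled ratio column by at most 0.0497. From log2 of the processed signals, the main measure here, it differed by up to 1.36 at single spots, with a correlation of at least 0.998 on every used array, and it had array medians from -0.19 to 0.03.

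Each array held 45219 spots, of which 3444 were controls and 22 others had no chromosome position. The remaining 41753 probes comprised 41458 nuclear and 295 mitochondrial ones. Spots marked as outliers in either channel were left out, which removed at most 0.606% of an array. Median signals over local background had a median of 77.1 in the sample channel (range 41.6 to 205) and of 56.7 in the reference channel (range 27.1 to 173). The number of arrays per group limits the precision of every group value.

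The main measure was log2 of the processed sample signal over the processed reference signal, centred on the array's median over nuclear probes, minus the median of the 10 progenitors at the same probe. A progenitor was set against the other 9. A chromosome was called gained or lost where the medians of its left and its right part, with equal numbers of probes, both reached 0.15 with the same sign. Because many changed chromosomes shift the median of an array, calls were also made after centring on the mode of the 16 chromosome medians (mode centring). Segments within chromosomes came from optimal partitioning with a penalty of 15 times the noise variance times the log of the probe number and at least 8 probes per segment. A segment was counted where its mean differed by at least 0.2 from its chromosome's median and it covered under 80% of the probes. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on gene means of centred ratios, not progenitor-subtracted, with the 2 compared groups in the fit). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 0.1. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

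The genome build of the probe positions is not given in the sources used here. Positions were taken from the newer of 2 array grids in the files, and genes were named where a probe's midpoint lay within a gene of the R64 annotation. This was checked in the data: only 3 of 275 tRNA genes held a probe midpoint, against 86 after a shift of 500 bases, so the probe design and the annotation share their frame. STE4 of the progenitors was not well above background in the sample on 20 of 50 spots, while its neighbours MGM1 and SAS5 were at -0.02 and -0.01. In all, 5637 protein-coding genes held at least 1 probe.

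HXT6 and HXT7, nearly identical neighbouring genes, held no probe, so the planned test of their probes could not be run. It was replaced, after the data had been seen, by the mean of the 16 probes between the outer ends of both genes, minus the median of chromosome IV, and a gain was called at 0.3. The ribosomal DNA and the CUP1 repeat were each measured by 1 probe and the 2-micron plasmid by none.

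Groups were compared by the ploidy of the founder and by generation, as the labels give them. Two-sided exact permutation tests compared mean numbers per clone, counting every split with a difference at least as large in size, and with 10 or more values in each group 100000 draws were used. Shares of clones were compared with Fisher's exact test and carry exact (Clopper-Pearson) 95% binomial intervals. P-values were adjusted by the Benjamini-Hochberg method within each family. They measure only the spread between clones. Scan days were numbered 1 to 7 in order of time from the file headers, and results were repeated within a scan day where it held both groups. Clones of generations 250 and 500 that share a well name were paired for a test of similarity over all 120 pairings of 5 wells.

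The named genes followed a rule fixed before the data were examined: counts by direction for 9 gene lists with 2 to 4 examples each; SNF3, HXT6, HXT7, MTH1, RGT1, SUC2 and IRA1 in any case; the 10 called genes with the largest difference per comparison, at most 1 per 20 kb; genes at segments found in at least 3 clones of a group; and chromosomes past the Fisher test, with XII and XIII in any case. The lists were hexose transport and glucose sensing, raffinose, sucrose and maltose use, glucose repression, Ras-cAMP and TOR signalling, spindle and chromosome segregation, tandem and subtelomeric repeats, the mitochondrial genome, the 2-micron plasmid, and auxotrophic markers with mating type.

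Alternatives fixed before the data were examined were call thresholds of 0.1 and 0.2, mode centring, no progenitor subtraction, normexp background correction with an offset of 50, the deposited value table, removal of 166 probes that were dim or saturated on any array, whole-chromosome medians, other segment settings, HXT6/HXT7 call levels of 0.2 and 0.5, medians over multi-copy probes, other gene thresholds and fits, slide as a block, and pairing by well. Normexp was run on median signals, since mean signals are absent from the files. For alternative settings the number of called genes is given in percent of the genes tested, a unit chosen after the data had been seen. Scan-day analyses, the runs without clone 2N_217 or the HXT6/HXT7 segment, the removal of 430 probes that varied between progenitors, the pairing by well with mode centring, the comparisons of wells with generations 35 and 55, and the comparisons of multi-copy DNA at generations 55 and 500 were added after the data had been seen.

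The methods were tested on simulated data. A chromosome gain of 0.2 added to progenitor profiles with added noise was called in 98.8% of 160 cases and one of 0.25 in 100%, with 0 calls on the other chromosomes. Each such case raised 1 chromosome only. A segment of 50 probes raised by 0.5 was recovered in 100% of cases, one of 16 probes in 84% and one of 8 probes in 60%. Segments of these lengths raised by 0.3 were recovered in 89, 55 and 50% of cases. No noise was added for the segments. After progenitor subtraction the median noise was 0.06 in progenitors, against 0.21 in 4N and 0.31 in 2N clones of generation 250. Recovery of segments at the noise of those clones was not measured. With the real gene variances, limma recovered 81 to 97% of genes changed by 0.3.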

Results

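The arrays measured DNA copy ratios across the genome of Saccharomyces cerevisiae, each sample against the same reference strain. They covered 10 progenitor strains, whose individual ploidies the labels do not give, and single-colony clones from populations founded by haploid (1N), diploid (2N) or tetraploid (4N) cells and grown in raffinose medium. At generation 250 there were 8 clones from 1N founders, 8 from 2N founders and 20 from 4N founders. Further 4N clones came from generation 35 (2 clones), generation 55 (6 clones) and generation 500 (8 clones). The last 4 arrays held strains built with 1 extra chromosome: a 2N strain with an additional XIII, a 4N strain with an additional XII and 2 4N strains with an additional XIII. The median probe noise was 0.18 on the log2 scale and ranged from 0.10 to 0.42 between arrays.

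The progenitors and the constructed strains showed what no change and a change of 1 copy look like on these arrays. Of the 10 progenitors, 0 had a called chromosome, and the largest chromosome value in any of them, regardless of sign, was 0.06 in size. The 2N strain with an extra chromosome XIII had an XIII value of 0.52, against 0.58 expected for 3 copies over 2. The 4N strain with an extra XII had an XII value of 0.24, and the 4N strains with an extra XIII had XIII values of 0.28 and 0.29, against 0.32 expected for 5 copies over 4. In the progenitors the XIII values lay between -0.01 and 0.02 and the XII values between -0.01 and 0.01. Each constructed strain had 1 called chromosome, the one named in its label. They also had called segments, 9 in the 2N strain, 46 in the 4N strain with XII, and 14 and 44 in the 4N strains with XIII, against at most 2 in a progenitor. Each constructed strain had such segments at the marker genes LEU2, TRP1, MET17 and STE4. Others recurred at the same position in several strains, such as VII from 777532 in the 4N strains. Before progenitor subtraction STE4 was near the reference, at -0.12 in the 2N strain and -0.18 in the 4N strain with XII. Its called segment thus reflects the low STE4 signal of the progenitors. Whether the other segments are copy changes was not tested.

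The comparison of founder ploidies asks whether populations of higher ploidy changed their chromosome numbers more. Whole-chromosome gains and losses were found in clones from 4N founders and in 0 of the 16 clones from 1N and 2N founders. At generation 250, 18 of 20 4N clones (90%, exact 95% interval 68.3 to 98.8%) had at least 1 called chromosome, against 0 of 8 1N clones and 0 of 8 2N clones (each 0 to 36.9%). The 4N clones carried 5.3 ± 5.03 called chromosomes (SD, n = 20), of which 3.45 ± 2.31 were gains and 1.85 ± 3.41 losses. Clones 4N_301 and 4N_337 had none.

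The share of clones with a called chromosome differed by 90 percentage points between 4N and 2N and by the same amount between 4N and 1N (Fisher's exact test, two-sided, adjusted p = 2.17e-05 for each, 3 comparisons). The mean number per clone differed by 5.3 in both comparisons (exact permutation test, n = 20 and 8, adjusted p = 0.0112). Against the progenitors the difference was also 5.3 (permutation test, p = 0.00264). Within scan day 3, which held 7 4N and 8 2N clones, the difference was 4.57 (exact permutation p = 0.0014). Within scan day 2, with 5 4N clones and 3 progenitors, it was 5.8 and did not pass (exact permutation p = 0.179). No scan day held both 1N clones and 4N clones of generation 250. The tests treat clones as independent. Several 4N clones shared a set of called chromosomes, as described below, and a common ancestor or carry-over between wells stays open. If these clones are related, the p-values here and for chromosome XIII are too small.

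**Figure D1:**
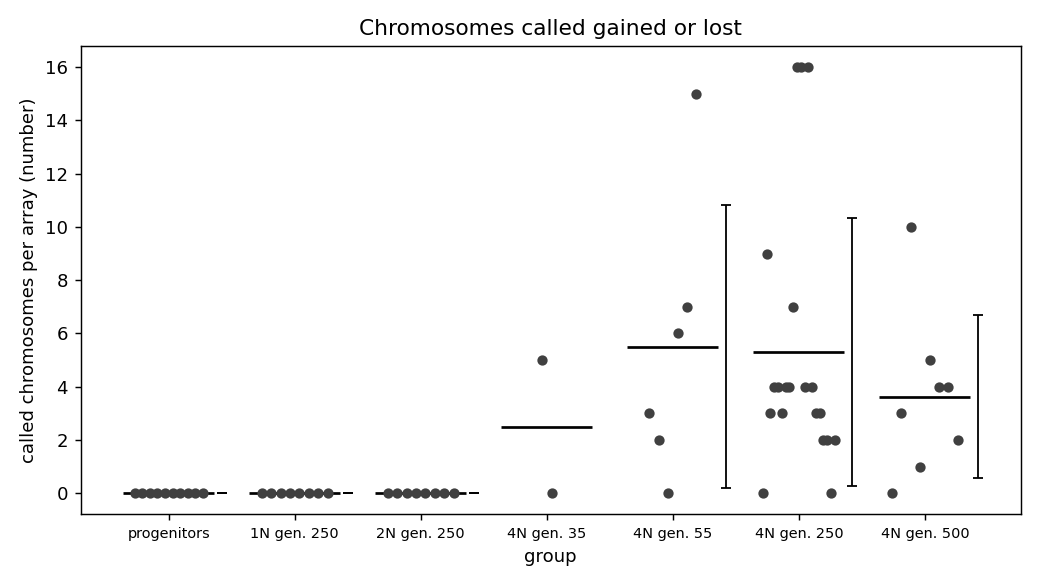
Number of called chromosomes per array in the progenitors and evolved clones. Each point is 1 array, horizontal lines are group means and whiskers 1 SD (groups of more than 2 arrays); the progenitors, 1N and 2N clones all lie at 0, and 18 of 20 4N clones of generation 250 lie above it.

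Chromosome XIII was gained in 18 of the 20 4N clones of generation 250 and in 0 of the 8 2N and 0 of the 8 1N clones (Fisher's exact test, two-sided, adjusted p = 2.32e-04 over 16 chromosomes against each group). Its mean value was 0.29 ± 0.11 (SD, n = 20). Under mode centring XIII was gained in 17 clones (adjusted p = 8.49e-04), with a mean value of 0.34 ± 0.15. Chromosome XIV was gained in 10 clones (adjusted p = 0.201), and III, IX and XII in 7 clones each (adjusted p = 0.24). VIII was gained in 6 clones (adjusted p = 0.377). Chromosomes IV, VI and XV were gained in 0 of the 20 clones, and IV and XV were each lost in 4. With mode centring the counts were 9 for gains of XIV, 7 for III, 6 each for IX and XII and 5 for VIII, and IV and XV were each lost in 2.

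Gains outnumbered losses by 1.6 chromosomes per clone at generation 250 (exact sign-flip permutation test, n = 20, p = 0.0321). Gains and losses here are relative to the level of each clone, not to the founder's 4 copies. By the step sizes described below, 13 of 17 clones with a gain at generation 250 lay nearest 1 copy added to 3. A gain over 3 copies would equal the founder's 4, so an excess over the founder is not shown, also for XIII. The balance of gains and losses moved with the centring, which sets the level counted as unchanged. With the array median as the zero level there were 69 gains and 37 losses, and with mode centring 59 gains and 17 losses. Clones 4N_318, 4N_319 and 4N_321 had all 16 chromosomes called with the array median and 6 each with mode centring. At a call threshold of 0.2 the excess of gains was 1.5 and did not pass (p = 0.0679, exact permutation).

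Several 4N clones of generation 250 carried the same set of gained chromosomes. Clones 4N_329, 4N_310, 4N_315, 4N_316 and 4N_305, from 5 different wells, each gained III, IX, XIII and XIV and no other chromosome. Clones 4N_330, 4N_304 and 4N_313, from 3 different wells, each gained VIII, XII and XIII. Clone 4N_335 gained XIII and lost XIV, clone 4N_336 gained XII and XIII, and clone 4N_338 gained III and XIII. Clone 4N_317 gained XIII and lost I, III, IV, IX, XV and XVI.

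**Figure D2:**
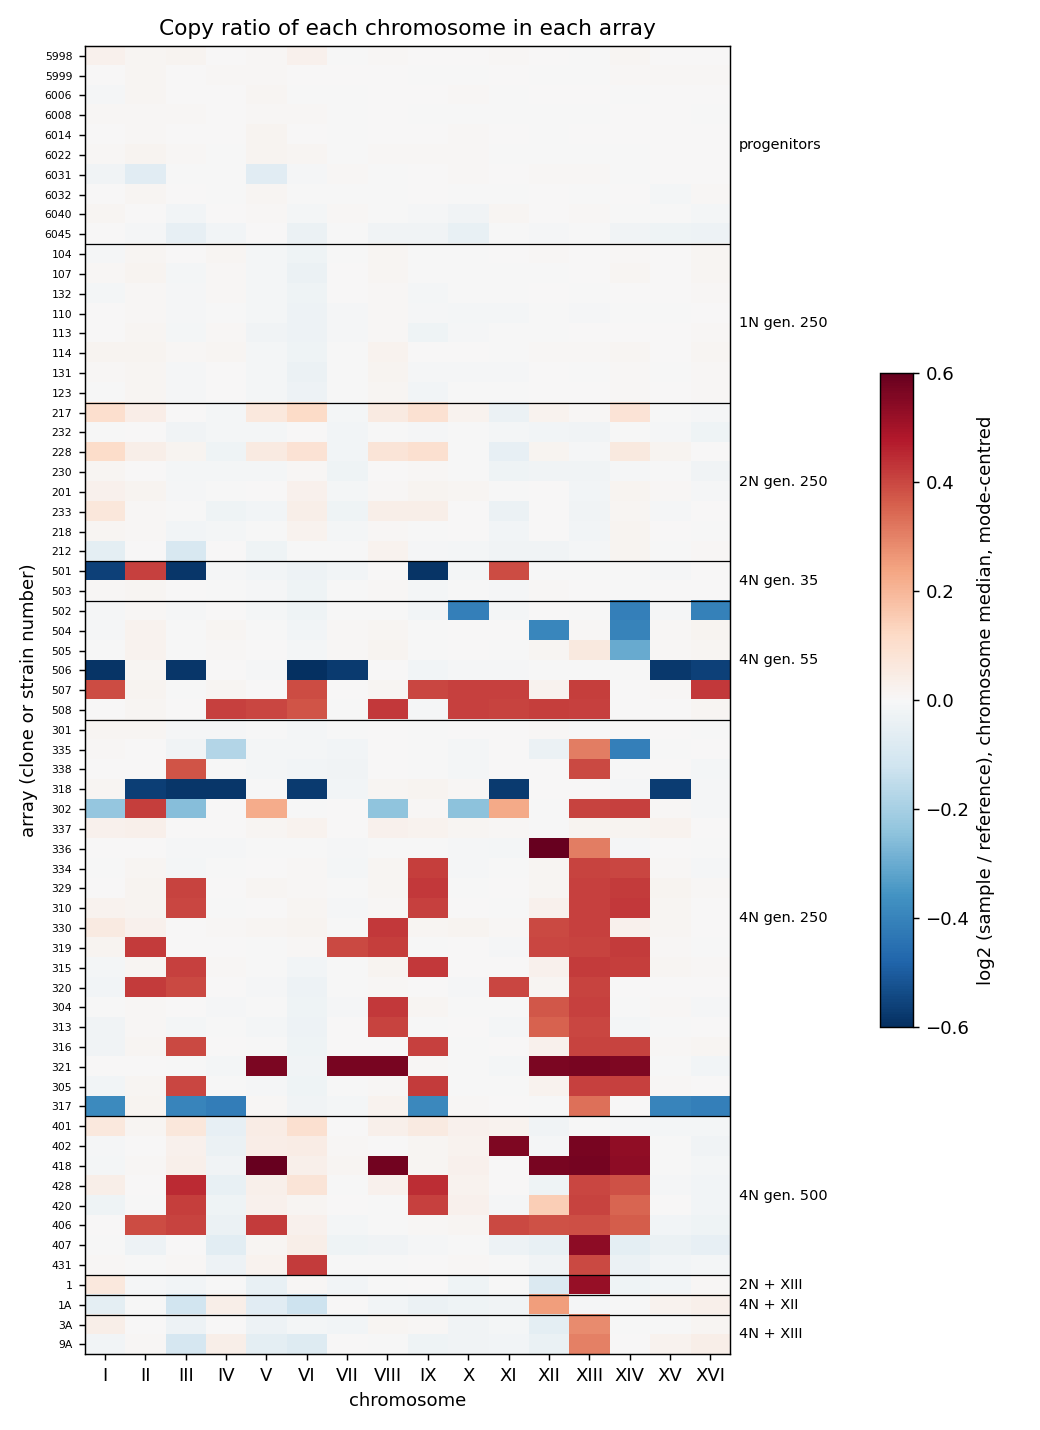
Copy ratio of each of the 16 chromosomes in each of the 66 arrays, as the median log2 ratio of sample over reference after mode centring (red higher, blue lower, arrays grouped as labelled at the right). Chromosome XIII is higher in 17 of the 20 4N clones of generation 250, and the 1N and 2N clones show no called chromosome.

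The time points ask when the changes arose in 4N populations. The earliest, generation 35, had called chromosomes in 1 of 2 clones, 4N_gen35_501, with 5. Called chromosomes were present at generation 55 in 5 of 6 clones (83.3%, exact interval 35.9 to 99.6%), and at generation 500, in 7 of 8 clones (87.5%, 47.3 to 99.7%). Chromosome XIII was gained in 2 of 6 clones at generation 55 and in 7 of 8 at generation 500. At generation 55, clones 4N_gen55_502, 4N_gen55_504 and 4N_gen55_506 had losses without a gain: X, XIV and XVI in 4N_gen55_502, XII and XIV in 4N_gen55_504, and I, III, VI, VII, XV and XVI in 4N_gen55_506. At generation 500, there were 26 gains and 3 losses, and the losses were IV, VII and XVI in clone 4N_gen500_406. With mode centring the losses numbered 17 at generation 250, 11 at generation 55 and 0 at generation 500.

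The number of called chromosomes passed no test between time points. Its mean was 5.5 ± 5.32 at generation 55 (SD, n = 6), 5.3 ± 5.03 at generation 250 (n = 20) and 3.62 ± 3.07 at generation 500 (n = 8). The differences were -0.2 between generations 250 and 55 (adjusted p = 0.959), -1.68 between 500 and 250 (adjusted p = 0.714) and -1.88 between 500 and 55 (adjusted p = 0.714, exact permutation tests, 3 comparisons). Paired by well, as a replicate block of the 5 wells present in both generations, the difference between 500 and 250 was -3.6 (exact sign-flip permutation p = 0.25). In 2 wells the number was equal, and in the other 3 it was lower at generation 500, for which 0.25 is the smallest p possible, so this test could not pass. With mode centring the differences were smaller, -0.55 between 500 and 250 (means of 3.25 and 3.8), -1.6 when paired by well and -1.08 between 500 and 55, while that between 250 and 55 was -0.53. Paired over the 4 wells present at generations 55 and 250, a pairing chosen after the data had been seen, the difference between 250 and 55 was 1.25 with either centring (exact sign-flip permutation p = 0.75). Generations 55 and 500 were each scanned on a day that held no clones of generation 250, so generation and scan day could not be separated here.

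Clones of generations 250 and 500 from the same well had chromosome profiles that were on average more alike than those of other pairings. In well F11 both clones gained III, IX, XIII and XIV, and their correlation over the 16 chromosomes was 0.985. This set is not particular to F11, since clones of other wells had it too, such as 4N_305 of well B4 and 4N_gen500_420 of well E8. In well E3 the clones shared V, VIII, XII, XIII and XIV, all 5 chromosomes called at generation 500 (r = 0.87). In well A3 they shared XI, XIII and XIV (r = 0.642), and in well G4 XIII alone (r = 0.281). In well A1 the clones had no called chromosome and r was -0.145. Over the 5 wells the mean correlation was 0.527, against 0.169 over all 120 pairings of the wells (one-sided exact permutation p = 0.00833, the smallest that 120 pairings can give). Earlier clones of the same wells were compared after the data had been seen. For generations 55 and 250 the mean correlation over 4 wells was 0.194, against 0.0382 over all 24 pairings, which did not pass (one-sided exact permutation p = 0.0833). In well G2 4N_gen55_504 shared the loss of XIV with 4N_335 (r = 0.567), in well A8 4N_gen55_505 shared no called chromosome with 4N_336 (r = 0.168), in well F11 4N_gen55_507 shared IX and XIII with 4N_329 (r = 0.0539), and in well A3 4N_gen55_502 shared the loss of X with 4N_302 (r = -0.0133), whereas 4N_gen35_501 of that well shared 4 chromosomes with 4N_302 (r = 0.57). Clone 4N_gen35_501 shared XI with 4N_gen500_402 (r = 0.321). In well G2 4N_gen35_503 shared no called chromosome with 4N_335 (r = 0.0789). Neither generation 35 clone shared a called chromosome with the generation 55 clone of its well (r = -0.0865 in A3 and -0.116 in G2). These correlations are across chromosomes, which are not independent replicates.

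Changes of parts of chromosomes were largest on chromosome IV. Clones 4N_301 and 4N_gen500_401, the generation 250 and 500 clones of well A1, both lost a stretch of about 100 kb: from 884215 to 987167 in clone 4N_301 (346 probes, -0.44 relative to the chromosome's median) and from 878256 to 987167 in clone 4N_gen500_401 (347 probes, -0.38). In clone 4N_335 the lower ratio began at 884691 and ran to the end of chromosome IV, apart from the HXT6/HXT7 interval. Clone 4N_gen55_505, which had no called chromosome, had higher ratios of chromosome XIII up to 190417 (0.26) and of XIV from 522226 to its end (0.32), each relative to the chromosome's median. Clone 4N_gen500_420 had a higher ratio of XII from 650798 to 824766 (0.27) and a lower one of XIV up to 96639 (-0.44). All positions are those of the array files, whose build is not given in the sources used here.

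**Figure D3:**
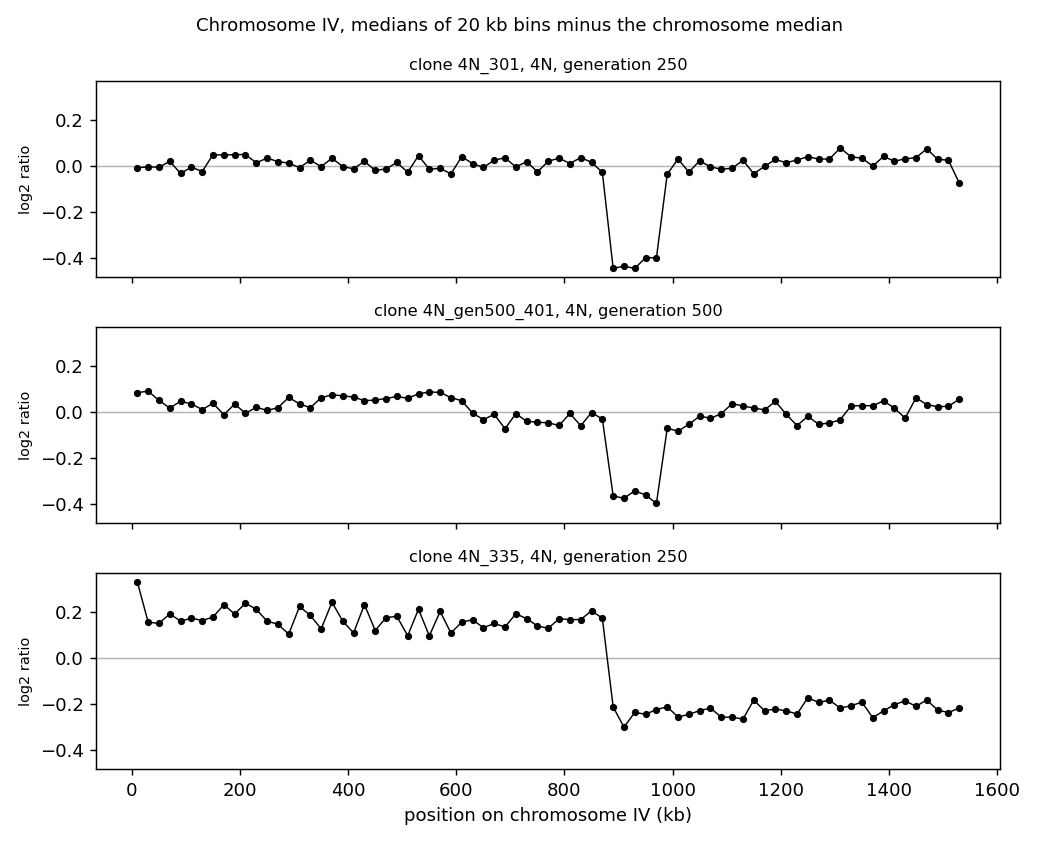
Chromosome IV in clones 4N_301, 4N_gen500_401 and 4N_335, as medians of 20 kb bins of the log2 ratio minus the chromosome's median (points), against position in kb. Clones 4N_301 and 4N_gen500_401, from the same well, share a lower stretch near 900 kb, and clone 4N_335 steps down near the same place and stays lower to the chromosome's end.

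At generation 250 the clones had on average 0.25 ± 0.46 segmental changes in 1N (SD, n = 8), 2.75 ± 5.37 in 2N (n = 8) and 0.85 ± 1.53 in 4N (n = 20), and progenitors 0.8 ± 0.79 (n = 10). The differences were -1.9 for 4N against 2N (adjusted p = 0.202), 0.6 for 4N against 1N (adjusted p = 0.385) and 2.5 for 2N against 1N (adjusted p = 0.0951, exact permutation tests). Clone 2N_217 alone had 16 of the 22 segments of the 2N clones, and without it the difference between 4N and 2N was -0.01 and that between 2N and 1N 0.61 (exact permutation, adjusted p = 0.122). The same stretch of XII, from 1040038 to 1071677, was called in 2N_217 and in a constructed 4N strain with an extra XIII. Whether all segments of 2N_217 are copy changes stays open. The difference between 2N and 1N passed with a penalty factor of 30, where it was 0.75 (exact permutation, adjusted p = 0.0303), or 0.73 without 2N_217 (adjusted p = 0.0303). This is the HXT6/HXT7 gain described below: all 6 segments of the other 2N clones lay there, and with that segment left out the difference at a penalty factor of 30 was 0, and at the main setting 1.75 with 2N_217 (adjusted p = 1) and -0.125 without it (adjusted p = 1), in comparisons chosen after the data had been seen. Besides HXT6/HXT7, segments found in at least 3 clones of a group were 3 regions in 4 of 8 clones of generation 500 each: III from 148731 to 151484 at SRD1, VIII from 211698 to 217115 across CUP1-1 and CUP1-2 (7 genes from CIC1 to RSC30), and XV from 742447 to 744208 at STE4, which is already lower in the progenitors. The stretch on III was also called in other groups, higher in 1N_104 (0.99), 4N_gen35_501 (1.21) and 4N_gen55_506 (0.92) and lower in PY6032 (-0.84) and 4N_336 (-0.56). Segments at STE4 were also called in progenitors, and its sample signal at generation 500 was not well above background on 15 of 40 spots. Generation 500 was scanned on a day of its own, so these are not shown to be changes of that generation.

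A focal gain lay between HXT7 and HXT6, which encode high-affinity hexose transporters, on chromosome IV from 1155967 to 1161427 (17 probes). It was present in 7 of 8 2N clones (87.5%, exact interval 47.3 to 99.7%), in 1 of 8 1N clones (12.5%, 0.316 to 52.7%) and in 7 of 20 4N clones of generation 250 (35%, 15.4 to 59.2%). The gained 2N clones had values from 2.30 to 3.35, and the gained 4N clones from 2.53 to 3.56. The 1N clone 1N_131 had 1.32, and its segment ended earlier, at 1159559 (16 probes). The 2N clone without the gain, 2N_233, had -0.06. At generation 500, clones 4N_gen500_420 (2.36) and 4N_gen500_431 (2.88) of 8 had the gain, and at generations 35 and 55 and in the progenitors 0 clones had it.

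The share with the gain was 75 percentage points higher in 2N than in 1N clones (Fisher's exact test, two-sided, adjusted p = 0.0303) and lower in 4N than in 2N clones, with a difference of -52.5 points (adjusted p = 0.0493). It differed by 22.5 points between 4N and 1N (adjusted p = 0.371). Within scan day 3, 4 of 7 4N and 7 of 8 2N clones had it, a difference of -30.4 points that did not pass (exact p = 0.282). The interval was chosen after the data were seen, in place of the gene probes the array lacks.

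**Figure D4:**
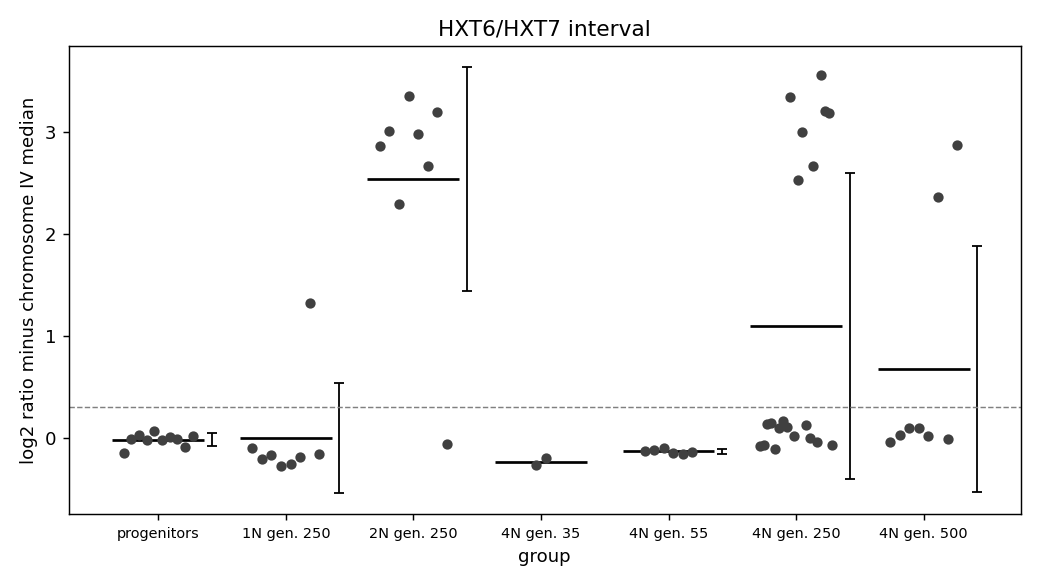
Log2 ratio of the 16 probes between HXT7 and HXT6 minus the median of chromosome IV, for each array, by group, with group means (lines), 1 SD (whiskers, groups of more than 2) and the call level of 0.3 (dashed). Of the 2N clones 7 of 8 lie at 2.30 or above, as do 7 of the 20 4N clones of generation 250.

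Mitochondrial DNA was lower relative to nuclear DNA in evolved clones of generation 250 than in progenitors, but not detectably so at generation 55. The mean log2 ratio over 295 probes was 0.28 ± 0.28 in progenitors (SD, n = 10), -0.12 ± 0.13 in 1N (n = 8), -1.20 ± 0.40 in 2N (n = 8) and -0.38 ± 0.56 in 4N clones of generation 250 (n = 20). The differences from progenitors were -0.40 (1N, adjusted p = 0.00521, exact permutation), -1.48 (2N, 8 of 8 clones below every progenitor, adjusted p = 1.03e-04, exact permutation) and -0.66 (4N, 12 of 20 below every progenitor, adjusted p = 0.00461, permutation). Clones were grown in raffinose medium and progenitors in rich medium before DNA extraction, per the labels. Within the 4N clones of generation 250 the mean was -0.73 on scan day 2, -0.85 on day 3 and 0.24 on day 5. Within scan day 2, the 4N clones differed from the 3 progenitors by -0.90 (exact permutation p = 0.0179, the smallest possible with 5 and 3 samples), which did not pass after adjustment (adjusted p = 0.0536). No scan day held progenitors together with 1N or 2N clones. The other generations were compared after the data had been seen. At generation 55 the mean was 0.17 ± 0.20 (n = 6), which differed from progenitors by -0.11 (adjusted p = 0.519, exact permutation), and at generation 500 it was -0.25 ± 0.19 (n = 8), a difference of -0.53 (1 of 8 below every progenitor, adjusted p = 0.00174, exact permutation). The 2 clones of generation 35 had a mean of 0.24. These generations were scanned on days without progenitors.

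**Figure D5:**
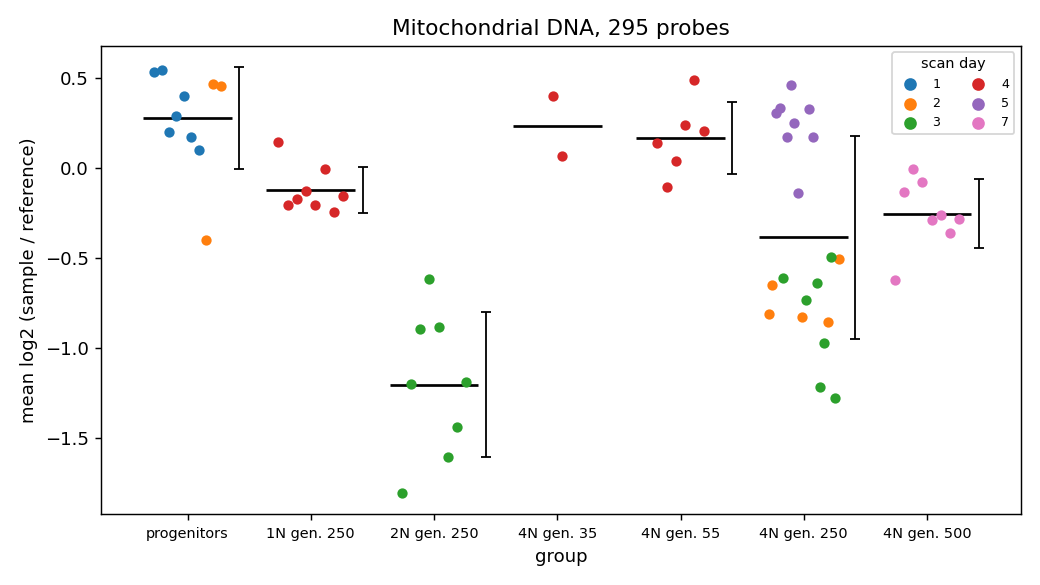
Mean log2 ratio of 295 mitochondrial probes per array, by group and coloured by scan day, with group means (lines) and 1 SD (whiskers, groups of more than 2). The 2N clones have the lowest mean, -1.20, and within the 4N clones of generation 250 those of scan day 5 lie higher than those of days 2 and 3.

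The single ribosomal DNA probe was higher in 1N clones than in progenitors by 0.62 (8 of 8 clones above every progenitor, adjusted p = 1.03e-04, exact permutation) and in 2N clones by 0.29 (5 of 8 above, adjusted p = 0.00461). In 4N clones the difference was 0.21 (adjusted p = 0.0921). The probe of the CUP1 repeat, which encodes metallothionein, was lower in 2N clones, with a difference of -0.52 (5 of 8 below every progenitor, adjusted p = 0.00117, exact permutation). It differed by -0.02 in 1N (adjusted p = 0.738) and -0.14 in 4N clones (adjusted p = 0.0576), and within scan day 2 the 4N difference was 0.0034. At generation 500 both probes were lower than in every progenitor in 8 of 8 clones, ribosomal DNA by a difference of -0.73 and CUP1 by -1.07 (each adjusted p = 6.86e-05, exact permutation), on a scan day that held no other group. At generation 55 neither passed, with differences of 0.08 for ribosomal DNA (adjusted p = 0.579) and 0.08 for CUP1 (adjusted p = 0.439, exact permutation). Compared within a scan day, also after the data had been seen, 2N clones were lower than 4N clones of generation 250 in CUP1 by a difference of -0.44 (adjusted p = 0.0233), and 1N clones were higher than 4N clones of generation 55 in ribosomal DNA by 0.55 (adjusted p = 0.021, exact permutation). The other comparisons within a day did not pass, with 0.0018 in ribosomal DNA for 2N minus 4N (adjusted p = 0.993) and -0.10 in CUP1 for 1N minus 4N of generation 55 (adjusted p = 0.0983), so the higher ribosomal DNA of 2N clones was seen only across days. Each of these values rests on 1 probe.

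The gene-level comparison asks which single genes changed their copy ratio. Against progenitors, limma called 1697 of 5637 genes (30.1%) in 4N clones of generation 250 (956 higher, 741 lower). Of the 10 genes named for their large differences, 3 lie on chromosome XIII and 3 on mitochondrial DNA. Of these 10, 5 were measured by 1 probe, among them CIN4 and CMC4. Those on XIII were CIN4 (0.79, adjusted p = 9.89e-05, 17 of 20 clones above every progenitor), CMC4 (0.73, adjusted p = 4.03e-06, 18 of 20) and PEX9 (0.72, adjusted p = 1.45e-07, 19 of 20). At generation 500, where 7 of 8 clones gained XIII, CMC4 had a mean of -0.31, so its value does not follow XIII alone. Among mitochondrial genes OLI1, which encodes a subunit of ATP synthase, was lower by a difference of -0.92 (adjusted p = 7.56e-07, 13 of 20 clones below every progenitor), COX3, a subunit of cytochrome c oxidase, by -0.79 (adjusted p = 1.06e-05, 11 of 20) and AI5_BETA by -0.76 (adjusted p = 6.17e-04, 13 of 20). Also among the 10 were YJR112W-A (-0.69) and YBL029C-A (0.66). The other 2 were URA3 and STE4, for which no difference is given, because in these 4N clones the reference signal of URA3 was not well above background on 70 of 80 spots and the sample signal of STE4 on 61 of 100. With fewer samples, within scan day 2, limma called 16 genes, all lower (458 at an unadjusted p under 0.05), and with scan day as a fixed term 197.

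Of 21 measured genes of hexose transport and glucose sensing, 4 were higher and 1 was lower in 4N clones of generation 250, and 4 were called when adjusted over the list alone. Among the higher ones were HXT14 (0.34), HXT2 (0.32) and YCK1 (0.25). HXT2 lies on chromosome XIII, gained in 18 of the 20 clones, and HXT14 on XIV, gained in 10. Gene values here are not relative to the chromosome, so they include whole-chromosome changes. SNF3, a glucose sensor, had a difference of -0.07 (adjusted p = 0.24), MTH1 -0.06 (adjusted p = 0.309) and RGT1, a repressor of hexose transporter genes, 0.03 (adjusted p = 0.669). HXT6 and HXT7 hold no probes. Of 7 measured genes of raffinose, sucrose and maltose use 1 was higher, SUC2, the invertase that cleaves raffinose (0.19, adjusted p = 0.0475), and 0 were called adjusted over the list alone. limma found SUC2 not called with normexp (0.12, adjusted p = 0.184) or with scan day as a fixed term (0.07, adjusted p = 0.967).

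Of 15 genes of glucose repression, 1 was higher (CAT8, 0.19) and 2 lower (SIP1 and REG1, each -0.15), and 3 were called adjusted over the list alone. Of 18 genes of Ras-cAMP and TOR signalling, RAS1 was lower (-0.18) and SCH9 higher (0.17), with 1 called adjusted over the list alone; IRA1, a negative regulator of Ras, had 0.02 (adjusted p = 0.85). Of 16 genes of the spindle and chromosome segregation, 4 were lower, among them SPC110 (-0.16) and MPS1 (-0.12), and 1 was higher, BUB3 (0.14), with 5 called adjusted over the list alone. CAT8 lies on chromosome XIII, and SIP1, REG1, SPC110 and MPS1 lie on IV. The mean value of IV in these clones was -0.11, or -0.06 with mode centring. These gene differences thus include the level of the chromosome and are not shown to be changes of single genes. Of 8 mitochondrial genes 7 were lower, also 7 adjusted over the list alone. The list of tandem and subtelomeric repeats had 2 measured genes, ENA1 (0.22) and ENA5 (-0.19), both called, also adjusted over the list alone. Of 14 marker and mating-type genes, BAR1 was higher (0.19) and TRP1 lower (-0.19). The test also called URA3, whose reference signal was mostly not well above background, and 1 gene of the list was called adjusted over the list alone. No gene of the 2-micron plasmid was measured.

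In the 1N clones limma called 2109 genes (37.4%, 1372 higher, 737 lower) and in the 2N clones 3460 (61.4%, 2085 higher, 1375 lower), although neither group had a called chromosome. Most differences were small: the median size of the 2109 differences in 1N clones was 0.16, and 1.56% of them reached 0.5. The genes below are those with the largest differences when at most 1 is taken per 20 kb, so that neighbours of a named gene are left out. In 1N they were YHL050C (1.64) and QCR10, a subunit of the cytochrome bc1 complex (0.86), followed by RSM19 (-0.73), YHR086W-A (-0.68), OLI1 (-0.67), ADD37 (0.67), YBL029C-A (0.67) and MPC1 (0.63). The rule also named URA3, with 24 of 32 reference spots not well above background, and MET17, with 24 of 24 spots not well above background in both channels, for which no difference is given. In 2N they were the mitochondrial AI5_BETA (-1.92) and SCEI (-1.86), beside which other mitochondrial genes such as ATP8 (-1.86) were left out by that rule, and SHU1 (1.33), ATP15 (1.28), SPC25 (1.23), YJR112W-A (-1.11), SPT4 (0.96), RIB7 (0.96), HUA1 (0.95) and YDR261C-D (-0.92). In each of these lists of 10 genes, 8 were measured by 1 probe. In the 2N clones, 12 of 21 genes of hexose transport and glucose sensing were higher and 1 lower, with 14 called adjusted over the list alone. The share called is near the 61.4% of all genes, so it does not set this list apart. Other lists moved too: 5 of 7 genes of raffinose, sucrose and maltose use were higher, and of 16 spindle and segregation genes 3 were higher and 8 lower. Of 8 mitochondrial genes 8 were lower. In the 1N clones, where 37.4% of all genes were called, 7 and 3 of the hexose list were higher and lower, and 6 mitochondrial genes lower.

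Against progenitors, 1493 genes were called in the 4N clones of generation 55 (26.5%, 803 higher, 690 lower), with the largest differences, by the same rule, in YHL050C (1.45), QCR10 (0.78), ADD37 (0.74), MCO12 (0.71), RSM19 (-0.70), LIP1 (0.63), UBC11 (-0.58), YHR138C (0.57), YBL029C-A (0.56) and MRPL31 (0.54). Of these, YHL050C, QCR10, ADD37, RSM19 and YBL029C-A were also named for the 1N clones, in the same directions. Both groups were scanned on day 4, which held no progenitors. Evolution, growth medium and scan day therefore cannot be told apart for these genes. Between generations 500 and 250 limma called 1591 (28.2%, 684 higher, 907 lower). The largest differences there, by that rule, were SHU1 (-1.10), RPE1, an enzyme of the pentose phosphate pathway (-1.06), YHL050C (1.03), CMC4 (-0.99) and SPC25 (-0.94), followed by YHR054C, which lies between CUP1-1 and CUP1-2 (-0.92), YJR112W-A (0.85), ATP15 (-0.85), RIB7 (-0.82) and FYV12 (-0.80). With well as a replicate block, in the 10 clones of wells present in both generations, 7.65% of genes were called. Of the 20 genes named for these 2 comparisons, 9 of each 10 had 1 probe. Progenitors of scan day 2 against progenitors of scan day 1, which were different strains, gave 1136 calls, and 4N clones of generation 250 gave 8 calls between scan days 2 and 3, 721 between days 2 and 5 and 903 between days 5 and 3.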

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

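The tests in this part were chosen after the results had been seen, except the comparison of progenitors between scan days and the tests of shared chromosome sets by shuffling and by correlation, whose bounds were written before they were run. Chance marks about 1 in 20 groups as holding an unusual sample, and 5 of 32 tested groups and measures did.

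Among the progenitors, strain PY6032 lay far below the others in mitochondrial DNA, at -0.40 against 0.10 to 0.54, and in the CUP1 probe, at -0.56 against -0.22 to -0.01. Among the 1N clones, 1N_131 stood apart with 1.32 in the HXT6/HXT7 interval. Among the 2N clones, 2N_217 had 16 segmental changes against at most 1 in the others, and 2N_233 had -0.057 in the HXT6/HXT7 interval against at least 2.30 in the others. The share of clones with the HXT6/HXT7 gain differed between founder ploidies, by 75 points for 2N minus 1N and by -52.5 points for 4N minus 2N. The difference of mitochondrial DNA from progenitors was -1.08 for 2N minus 1N (exact permutation p = 1.55e-04). All 2N clones were scanned on day 3 and all 1N clones on day 4, so ploidy and scan day cannot be told apart here, and within day 3 the 2N clones differed from 4N clones by -0.35, which did not pass (exact permutation, adjusted p = 0.0983), and within day 4 the 1N clones differed from 4N clones of generation 55 by -0.29, which passed (adjusted p = 0.021). Clone 4N_gen35_501 of generation 35, which is in no comparison of groups, had 5 called chromosomes.

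In 1N and 2N clones without a called chromosome, limma called 2109 and 3460 genes. For 1N clones, copy changes as the source of most calls are argued against. A change in a single clone hardly moves a mean over 8, so each clone was compared with the progenitor mean: for 9.06% of the 2109 genes (3.94% of those with at least 3 probes) at least 1 clone differed by 0.4 or more in the direction called, while 1 extra copy adds 1 in a haploid and 0.58 in a diploid clone. The bar set for this was 10%, and the clones' ploidy was not measured. Scan day stays open: progenitors of day 2 against progenitors of day 1 gave 1136 calls, but these were different strains of unknown ploidy, so strain and scan day cannot be told apart, and 4N clones of generation 250, which differ in their called chromosomes, gave 8 between days 2 and 3, 721 between days 2 and 5 and 903 between days 5 and 3. Groups also differed within a day: on day 3, 4N against 2N clones gave 1445 calls (1000 relative to the chromosome's median), and on day 4, 4N clones of generation 55 against 1N clones gave 268 (96). These groups lay on different slides. The 2 groups of day 4 shared named genes against progenitors, such as YHL050C, at 1.64 in 1N clones and 1.45 at generation 55. Random splits of the samples do not give such counts: for 1N clones the real count was 2109 and the highest of 99 other splits 1290, for 2N 3460 and 0, for 4N of generation 250 1697 and 156, for generation 55 1493 and 439, and for generation 500 against 250 1591 and 429, so that 1 of 100 splits, the real one, was as large each time. Chance alone is thus unlikely, but a rank of 1 in 100 cannot exclude it, and the splits ignored scan day and slide. No scan day held progenitors and 1N or 2N clones, so biology of these clones against progenitors cannot be told apart from scan day and slide.

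Mitochondrial DNA was lower in evolved clones of generation 250 than in progenitors, while generation 55, scanned on another day than progenitors, differed by -0.11 (exact permutation, adjusted p = 0.519). Scan day as the whole cause is argued against by the difference of -0.90 within scan day 2, where each of 5 4N clones lay below each of 3 progenitors (exact permutation p = 0.0179, the smallest possible). Scan day may account for part of it, since days 5 and 3 differed by 1.08 within 4N clones of generation 250 (exact permutation p = 1.55e-04). The growth medium, which generation 55 shared with generation 250, stays open, because 0 groups were measured from both media. The evolution itself and the ploidy of the founder stay open as well, untested.

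Clones of 4N founders from different wells carried the same set of called chromosomes. Independent changes at the observed frequency of each chromosome do not give this: 13 pairs of clones shared a set of at least 2 chromosomes, against 0.285 on average and at most 7 when each chromosome's calls were shuffled between clones (p = 1e-05, the smallest that 100000 shuffles can give). The same DNA on several arrays is argued against for clone 4N_330 and each of 4N_304 and 4N_313, since the HXT6/HXT7 interval differed by at least 2.52 within these 2 pairs. For the other pairs it could not be excluded, since the median correlation of probe values of same-set pairs on a scan day, 0.844, lay within the range of other pairs, 0.364 to 0.98; that range was too wide for the bound set beforehand to decide. A common ancestor or carry-over between wells stays open too, as 1 of the 2 shared sets held clones that differ in the HXT6/HXT7 gain, which could have arisen later. Joint selection of the chromosomes is a biological explanation that was not tested.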

How the results depend on the processing

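The HXT6/HXT7 interval, the scan-day analyses and tests, pairing by well with mode centring and of generations 55 and 250, multi-copy DNA at generations 55 and 500 and within scan days, the runs without clone 2N_217 or the HXT6/HXT7 segment, the removal of probes that varied between progenitors and the leave-one-out runs of wells were chosen after the results had been seen; all other alternatives were set before the data were examined.

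Of the alternatives run for the main results, most values stayed on their side of the threshold and in their direction (or close to the main value), among them every alternative for the share of clones with a called chromosome in 4N against 1N and 2N. Leaving out 1 well at a time, the mean same-well correlation ranged from 0.412 to 0.694, and leaving out 1 of the 4N strains with an extra XIII gave 0.28 to 0.29. Beyond the main results, alternatives were compared for SNF3, MTH1, RGT1, SUC2 and IRA1, and for the numbers of 4N clones with XII or XIII gained. Of these values, 243 kept their side or stayed close to the main value, 13 weakened and 5 became stronger. The other named genes were not checked in this way. The cause of the following changes was not tested, except that some settings hold fewer samples.

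At a call threshold of 0.2 the excess of gains over losses in 4N clones was 1.5 and no longer passed. Within scan day 2, with 8 samples, the difference in called chromosomes between 4N clones and progenitors was 5.8 and no longer passed, nor did the mitochondrial difference of -0.90, and the CUP1 difference turned to 0.0034. Within scan day 3 the HXT6/HXT7 difference of 4N and 2N was -30.4 points and no longer passed. The segment difference of 2N and 1N passed with a penalty factor of 30 (0.75), with at least 15 probes (2.62) and without variable probes (2.5). Clone 2N_217 made up most of the last 2: without it each of these 3 settings gave 0.73, which still passed, and the main setting 0.61, which did not. All 6 main segments of the other 2N clones were the HXT6/HXT7 gain. Without that segment the difference of 2N and 1N passed at none of these settings, and without 2N_217 as well it was -0.125 at the main setting and 0 at the 3 others. The difference of 4N and 2N then turned to 0.5 at the main setting, 0.45 with at least 15 probes and 0.25 at the other 2 (also with 2N_217 for the penalty factor of 30), and did not pass. Paired by well, the difference in called chromosomes between generations 250 and 55 turned to 1.25 with either centring. With normexp the ribosomal DNA difference of 4N clones (0.34) and the CUP1 difference of 1N clones (-0.18) passed. The constructed strains moved with normexp, to 0.74 for 2N with XIII, 0.31 for 4N with XII and 0.36 for 4N with XIII, and with mode centring, to 0.25 for XII and 0.29 for XIII in 4N. Without progenitor subtraction XII was 0.25.

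The share of genes called also moved, from 37.4% in 1N, 61.4% in 2N, 30.1% in 4N of generation 250, 26.5% at generation 55 and 28.2% for generation 500 against 250. With a least difference of 0.2 it was 10.8% (1N), 40.4% (2N), 16.9% (4N, generation 250) and 14.3% (generation 55), and with no least difference 69.7% in 1N. With all groups in 1 fit it was 9.92% in 1N and 11.7% at generation 55. With slide as a random block it was 15.01% at generation 250, 17.5% at generation 55 and 18.5% for 500 against 250. With scan day as a random block it was 23.5% in 1N, 13.5% in 4N of generation 250 and 7.13% for 500 against 250. With scan day as a fixed block it was 3.49% at generation 250, and within scan day 2 0.284%. For 500 against 250, values relative to the chromosome's median gave 47.2% and the well block, with fewer samples, 7.65%. The median signal over background of an array was at least 27.1 in either channel. Whether it limits chromosome values was not tested apart from normexp, which moved the constructed strains, and genes and repeats with 1 probe rest on single spots.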

Other observations

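The tests in this part, of the chromosome XIII values, of the segment ends and of the step sizes, were all chosen after the results had been seen.

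The progenitors and all evolved clones differed from the reference at marker genes, which were looked at after their values had been seen. URA3, an enzyme of uracil synthesis, was well above background in the sample on every spot of the progenitors, and in the reference it was not so on 25 of 40. STE4, the beta subunit of the G protein of the mating response, was well above background in the reference on every spot and not so in the progenitors on 20 of 50. In the constructed strains STE4 was near 0, at -0.12 in the 2N strain with XIII. MET17 was well above background in the sample on every spot of the constructed strains, whereas in the 1N clones it was not on 24 of 24.

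The generation 35 clones were in no comparison of groups. Clone 4N_gen35_501, from well A3, gained II and XI and lost I, III and IX, and clone 4N_gen35_503, from well G2, had no called chromosome.

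The called chromosomes of evolved 4N clones took few step sizes. With mode centring, 25 of 27 clones with a gain had gains that spanned at most 0.1. A clone with 1 gain counts here with a span of 0, as for both clones between 0.31 and 0.33 below. Of the 24 clones with several gains, 2 spanned more than 0.1. The median gain of the 25 clones lay between 0.39 and 0.42 in 19 clones, between 0.53 and 0.58 in 4 and between 0.31 and 0.33 in 2. These values are near the steps of 0.42, 0.58 and 0.32 that 1 copy adds to 3, 2 and 4 copies. A step of 0.58 is also given by 2 copies added to 4. None of the 4 clones at that step had a lost chromosome that could tell these apart. A candidate explanation is that the base copy number differed between these clones and that many had 3 copies of most chromosomes. In clones with both gains and losses the base copy number can be solved from each: 4N_gen35_501 gave 3.12 and 3.00, 4N_335 gave 4.22 and 4.04, 4N_317 gave 3.88 and 4.15, and 4N_302 gave 3.08 and 6.45, so that 3 of the 4 gave the same whole number. The 2 clones not counted mixed unequal steps, 4N_336 with XII at 0.70 and XIII at 0.31, and 4N_302 with V at 0.22 and XI at 0.23 beside II, XIII and XIV from 0.41 to 0.42. The constructed strains, solved in the same way, gave 2.28 for 2N and 4.32 to 5.28 for 4N, so the scale is not exact, and DNA content per cell was not measured here.

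A larger value of chromosome XIII at generation 500 than at 250 was tested as a sign of fewer base copies. The difference was 0.07 (exact permutation p = 0.351), and generation 500 was scanned on a day of its own. Among clones of generation 250 with a gain of XIII, the means of the scan days spanned 0.050. This is less than the difference but close to it, so the ratio scale of the scan day stays open. In generation 500 clones the other gained chromosomes had 1.00 times the XIII value (median of 6 clones, 0.963 to 1.06), which argues against extra copies of XIII alone. By the step sizes above, 3 of the 7 clones with a gain at generation 500 lay nearest 1 copy added to 2, against 2 of 17 at generation 250. Of those 2, 4N_336 mixed unequal steps. The same step is given by 2 copies added to 4, and this difference was not tested. Of 8 clones of generation 500, 3 lay nearer the 2N than the 4N constructed strains, against 7 of 20 of generation 250 (Fisher's exact p = 1); the midpoint of 0.41 fell within the main cluster of values, which leaves this undecided.

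The ends of large segmental changes may lie at repeated elements. Of 11 segment ends in 4N clones, 7 (63.6%) were within 2 probes of a gap in the probe coverage of at least 4 kb. Clones 4N_301 and 4N_gen500_401, from the same well, share 2 of these ends or nearly so, and with their segment used once it was 5 of 9 ends (55.6%), against 4.17% on average for random breaks (p = 1e-04, the smallest that 10000 draws can give). The annotation places open reading frames of Ty elements within 5 kb of most of these ends, such as YDR210C-D and YDR261W-B at both ends of the chromosome IV loss in clones 4N_301 and 4N_gen500_401.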
